A study of Homo sapiens with 15 samples.

How the data were processed

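Gene expression was measured on 15 Affymetrix arrays (Human Genome U133 set, array A), each hybridised with biotin-labelled total RNA from A673 cells, per the labels. The deposited values are signal intensities on a linear scale, 1 per probe set and array, where a probe set is a group of short probes against 1 transcript. The summary method, the software and the scaling rule behind these intensities are not given in the sources used here. On every array 100% of the deposited intensities were whole multiples of a constant step, within 0.05 of a step. The step was 0.1 on the run 1 array of induced 0 h and differed on each other array by a factor between 0.654 and 1.28, a pattern left by multiplying the signals of each array by 1 factor. Median signals still ranged from 22.7 to 34.7 over the arrays, so array distributions were not equal as deposited. Detection calls were not used here. Between 31.8% and 43.1% of probe sets per array had a signal under 16, and differences among such dim probe sets are hard to tell from background.

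From these intensities, log2(signal + 16) was computed and quantile-normalized between arrays with limma 3.58.1 in R 4.3.3. All log2 changes and folds are on this scale, which shrinks the change of dim genes. No fold is given against a group mean below the filter level, called background in the report. The table holds 22283 probe sets, of which 68 are control probe sets that were left out of all tests. By the platform annotation, 19071 probe sets have 1 gene symbol, 1043 have several and 2169 have no listed symbol, including 62 controls. Symbols were looked up by gene number in the RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 differed from the current symbol. Probe sets below the 30th percentile of the mean log2 value over all arrays (4.78, a signal of 11.5) were left out. Each gene was represented by its brightest probe set with a single symbol, which left 9277 genes for testing. Among 57 genes named from the main comparison, 24 had more than 1 probe set above that level, and 45 of their 50 further probe sets moved in the same direction as the one used. The 5 that did not belong to CD44, PGF, EWSR1 and FLI1. NR0B1, which the rule for named genes lists, has no probe set with a single symbol in the annotation used and was not analysed here.

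Samples were grouped by the treatment and time in their labels. In the main comparison, induced 24, 48 and 72 h (6 arrays, called late induced) were set against induced 0 h, uninduced 24 h and uninduced 72 h (5 arrays, called not induced) in a 2-group limma fit. All other comparisons came from 1 limma fit over the 8 groups of all 15 arrays, so that every group shared the estimate of the spread. The lone uninduced 24 h array was assumed to vary like the other groups. Both fits used moderated statistics with an intensity trend (eBayes with trend=TRUE), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A moderated F-test covered any change over the induced time course. The effect of induction at 72 h was tested against that at 24 h as an interaction contrast, which was added after seeing the data.

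A set of 25 gene lists with 714 different genes was fixed from general knowledge before the data were examined, as were the comparisons and tests other than the interaction, the alternative settings and the rule for named genes. Of these genes, 7 had no unique current symbol and were left out, and lists with fewer than 5 tested members were not tested, which left 24 lists. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. With an estimated correlation, camera also takes its degrees of freedom from the arrays and not from the number of genes. A weaker result there is therefore not due to correlation between genes alone. For cholesterol synthesis genes in uninduced 72 h against induced 0 h, the estimated correlation was -0.0086, below the preset one. Their unadjusted camera p still rose from 3.26e-17 to 3.96e-05. The rule named FLI1, EWSR1, NKX2-2 and NR0B1 in every array. It then took the 10 largest changes in each direction among genes called in the main comparison with the same sign in both runs, and the 5 largest in each direction in other comparisons. From each list described it took up to 4 members with the smallest p, with both extremes for a list that went both ways. Where no gene was called, it took the 3 smallest p, and for the F-test the 5 smallest. Genes named outside the rule are marked as chosen after their values were seen.

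The pipeline was tested on simulated arrays with the means and residual spread of the real ones. In the comparison of late induced with not induced arrays (9263 genes after the filter), 27.6% of genes changed by 0.5 on the log2 scale were recovered, 84.7% of those changed by 1 and 100% of those changed by 2, and 8.09% of the calls were false. For induced 72 h against uninduced 72 h (9271 genes), 1.64%, 18.5% and 81.5% were recovered at these sizes, with 4.35% of the calls false. The F-test was run on these same simulated arrays, in which only induced 72 h carried a change, and recovered 0%, 9.23% and 73.8%. These rates do not apply to genes that change at several times. Camera called the list shifted by 0.5 and 0 of 24 unchanged lists in the simulated comparison of late induced with not induced arrays. The simulated genes varied independently of each other, so this does not show how often camera falsely calls lists of correlated genes. The number of arrays limits the precision: the median standard error of a log2 change was 0.16 for 6 arrays against 5, 0.26 for 2 against 2, and 0.31 for 2 against 1.

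Alternatives were the run as a block, no filter, a filter at the 50th percentile, values as given without quantile normalization, an offset of 64, the mean of all probe sets of a gene, no intensity trend, a fit on only the arrays compared, uninduced arrays alone as controls, the estimated correlation between genes, and leaving out each array in turn. A run without the 2 arrays with the largest rescaling factors, camera with the estimated correlation for the timing of the response, and the alternatives for the interaction were added after seeing the data. Figures were drawn with matplotlib.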

Results

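A673 is an established Ewing sarcoma cell line, and the derivative profiled here, labelled Tet-A673/EF-2-RNAi, belongs to an inducible-rescue experiment. From what is known of the study, and not from the labels, such cells carry RNA interference against their own EWS/FLI, the fusion oncoprotein of EWSR1 and the ETS transcription factor FLI1, together with a regulated EWS/FLI construct that restores it on induction. The question was then which genes respond, and when, once the fusion is restored. Induced cells were profiled at 0, 6, 12, 24, 48 and 72 h with 2 arrays each (run 1 and run 2), uninduced cells at 72 h with 2 arrays and uninduced cells at 24 h with 1 array, from run 2. The labels do not say that the runs were separate cultures, so p-values measure only the spread between these samples, which may be technical. Rank correlations between any 2 arrays, which rescaling does not change, ranged from 0.889 to 0.954 across probe sets, so no array was a rescaled copy of another. Pairs of arrays from the same group correlated at 0.945 to 0.962 across genes, and the lowest mean correlation with all other arrays was 0.93, for the run 1 array of induced 72 h.

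FLI1 signal was higher after induction. Its brightest probe set had a signal of 1194 ± 137 (SD, n = 6) in the late induced arrays (24, 48 and 72 h) and 613 ± 179 (SD, n = 5) in the arrays that were not induced (induced 0 h, uninduced 24 h and uninduced 72 h). This was a 2.08-fold difference (log2 change 1.05 ± 0.16 SE, limma adjusted p = 0.00035). In run 1 the signal was 548 at 0 h, 844 at 6 h, 843 at 12 h, 1423 at 24 h, 1178 at 48 h and 1003 at 72 h, and 792 in uninduced cells at 72 h. In run 2 it was 613, 1215, 1096, 1241, 1152 and 1168 at these times, and 349 and 763 in uninduced cells at 24 and 72 h. The other 2 FLI1 probe sets were dim, with mean signals of 29.5 against 30.4 and of 48.6 against 52.8, and showed no detectable difference (log2 change -0.01 ± 0.23 and -0.03 ± 0.13 SE). With the mean of all FLI1 probe sets the change was 0.34 and was not called. Where the probe sets lie relative to the fusion or the construct is not given in the sources used here, so the level of FLI1 tells neither native FLI1 nor either form of the fusion apart.

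NKX2-2, a homeobox gene known as a target of EWS/FLI, had a signal of 357 ± 71.9 (SD, n = 6) in late induced arrays and 162 ± 26.6 (SD, n = 5) in arrays that were not induced. The 2.24-fold rise had a log2 change of 1.17 ± 0.13 (SE, adjusted p = 1.55e-05). By array, the NKX2-2 signal in run 1 was 157, 153, 247, 301, 440 and 311 at 0, 6, 12, 24, 48 and 72 h, and 176 without induction at 72 h. In run 2 it was 167, 204, 272, 317, 314 and 458, and 119 and 190 without induction at 24 and 72 h. EWSR1, the other partner gene of the fusion, showed no difference on its brightest probe set, with signals of 187 ± 28.4 (SD, n = 6) and 202 ± 25.8 (SD, n = 5) and an adjusted p of 0.996. EWSR1 ranged from 148 to 230 over all arrays.

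**Figure D1:**
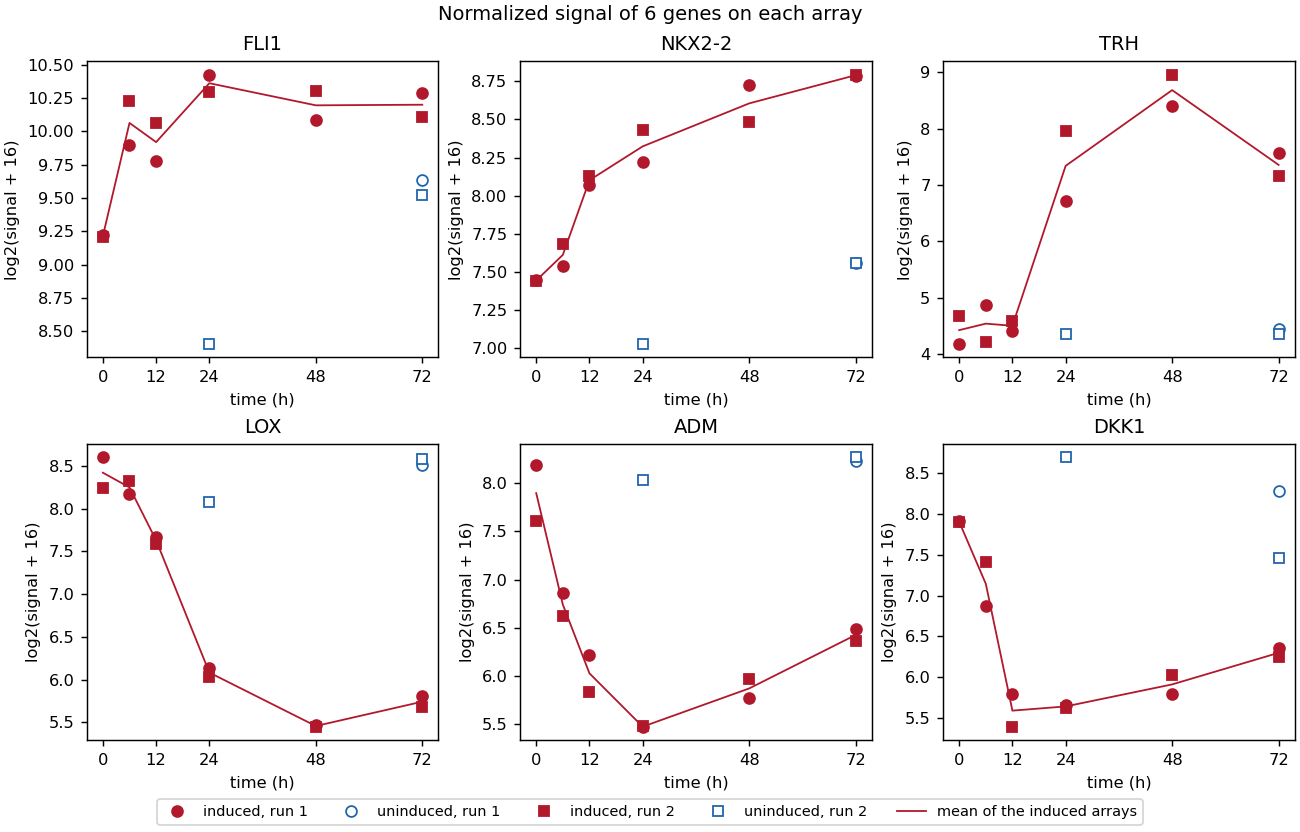
Normalized signal, log2(signal + 16), of 6 genes against time in hours. Each point is 1 array, filled for induced and open for uninduced cells, circles for run 1 and squares for run 2, and lines join the means of the induced arrays. FLI1 stood above its 0 h level from 6 h, NKX2-2 climbed to 72 h, TRH left its baseline between 12 and 24 h, and LOX, ADM and DKK1 were low in all late induced arrays and high in the uninduced ones.

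TRH, which encodes the precursor of thyrotropin-releasing hormone, was higher in late induced than in not induced cells (log2 change 3.38 ± 0.29 SE, n = 6 against 5), and so was ELN, which encodes elastin (2.34 ± 0.17 SE). Without induction both had a mean normalized value below the filter level of 4.78 (4.41 and 4.55), at background, so the offset sets the size of their changes and no fold is given. NGFR, the low-affinity nerve growth factor receptor, was 5.01-fold higher (2.33 ± 0.23 SE). Its not induced mean of 4.81 was close to the filter level, so the offset sets part of that fold too. LOX, the lysyl oxidase that cross-links collagen and elastin, was 6.25-fold lower (-2.64 ± 0.15 SE), the secreted protein gene IGFBP7 5.76-fold lower (-2.53 ± 0.38 SE) and CD44, a hyaluronan receptor, 5.21-fold lower (-2.38 ± 0.24 SE). The IGFBP7 means at 48 and 72 h were at background (4.23 and 4.22), so the offset sets part of its fold.

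The other large increases were in the cation channel gene TRPM4 (3.89-fold), the transcription cofactor gene LBH (3.77-fold), IGFBP4 (3.67-fold), the carboxylesterase gene CES1 (3.54-fold), FCGRT, which encodes the neonatal Fc receptor (3.49-fold), the pseudokinase gene TRIB2 (log2 change 1.58 ± 0.13 SE) and the aldo-keto reductase gene AKR1B10 (2.97-fold). The other large decreases were in the matricellular protein gene POSTN (4.44-fold), the vasodilator peptide gene ADM (4.42-fold), the Wnt inhibitor gene DKK1 (4.29-fold), the placental growth factor gene PGF (4.23-fold), the ectonucleotidase gene NT5E (4.12-fold), the small heat shock protein gene CRYAB (3.97-fold) and CCN2, or connective tissue growth factor (3.87-fold). The adjusted p of these 20 genes ranged from 3.93e-09 for CES1 to 0.000741 for AKR1B10. For CD44 and PGF, a further probe set moved the other way, by 0.48 and 0.22, without being called. That of CD44 was dim (mean log2 value 4.82), and the other CD44 probe sets above the filter level fell. The only other PGF probe set was about as bright as the one used (7.999 against 8.094). Its change was 0.22 ± 0.11 (SE), so the fall of PGF rests on the probe set used alone. A further probe set of ELN changed by 0.23 ± 0.23 (SE). With the mean of all probe sets the changes were -1.49 for CD44, -0.93 for PGF and 1.28 for ELN. With an offset of 64, which shrinks the change of dim genes, they were 1.99 for TRH, 1.23 for ELN, 1.31 for NGFR, 1.10 for TRPM4, 1.18 for IGFBP4, 0.92 for AKR1B10, -1.42 for IGFBP7 and -1.26 for NT5E, and all stayed called.

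With limma, 462 of 9277 genes were called, of which 192 were higher and 270 lower in late induced cells. All 462 had the same sign in both runs, which a choice made on both runs together favours, so that is not independent replication. From values as given 375 genes were called, 102 higher and 273 lower, so the share of higher genes was 27.2% in place of 41.6%. At least 2-fold changes were found in 56 higher and 72 lower genes. When only the 3 uninduced arrays served as controls, 296 genes were called, of which 280 were among the 462. The 2 arrays with the largest rescaling factors, induced 48 h run 2 and induced 72 h run 1, both lie on the late induced side, and 398 genes were called without them, 355 of them shared.

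Genes listed as activated by EWS/FLI rose as a group. Of 47 tested members, 15 rose, 3 fell and 29 were not called (17 and 7 when adjusted over the list alone). LBH rose 3.77-fold (log2 change 1.91 ± 0.13 SE), FCGRT 3.49-fold (1.81 ± 0.16 SE) and STEAP1, a cell surface member of the STEAP metalloreductase family, 2.20-fold (1.14 ± 0.11 SE). PHLDA1 fell 3.69-fold (-1.88 ± 0.19 SE), and the other 2 that fell, named after their values were seen, were UPP1 (-0.97 ± 0.19 SE) and PDGFC (-0.84 ± 0.14 SE). Camera gave the list an adjusted p of 4.55e-07, and an adjusted p of 0.0138 with an estimated correlation. Genes listed as repressed by EWS/FLI fell as a group. Of 25 tested, 11 fell and 1 rose (11 and 1 when adjusted over the list alone), with LOX, CD44, DKK1 (-2.10 ± 0.19 SE) and NT5E (-2.04 ± 0.18 SE) at the lead and the pseudokinase gene TRIB1 (0.71 ± 0.16 SE) as the exception. The call of TRIB1 was lost with values as given, and PHLDA1 changed by -1.09 with the mean of its probe sets and by -1.22 with an offset of 64. The adjusted p of this list was 2.1e-09, and 0.0104 with an estimated correlation. Both lists were drawn from general knowledge of EWS/FLI studies, to which experiments of this kind contributed, so their directions, and the counts adjusted over the list alone, are not independent evidence. The repressed list also shares members with lists described below. These are CCN2 with TGF-beta response genes, TNC with extracellular matrix genes, and ITGA1, ZYX and CNN3 with actin cytoskeleton and adhesion genes. Shifts of those lists are thus not fully separate from that of the repressed list.

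Extracellular matrix genes fell. Of 36 tested, 19 fell, 3 rose and 14 were not called (22 fell and 3 rose when adjusted over the list alone). POSTN fell 4.44-fold (log2 change -2.15 ± 0.26 SE), LOXL2, a lysyl oxidase relative, 2.81-fold (-1.49 ± 0.16 SE) and COL4A1, a basement membrane collagen, 2.70-fold (-1.43 ± 0.15 SE). TIMP3, an inhibitor of matrix metalloproteinases, rose 1.99-fold (0.99 ± 0.13 SE), and so did TIMP1 (0.55 ± 0.10 SE) and FBLN5 (0.57 ± 0.13 SE), which were named after their values were seen. The median change of the list was -0.62 (camera adjusted p = 1.78e-13, and adjusted p = 0.0138 with an estimated correlation). Of 30 actin cytoskeleton and adhesion genes, 9 fell and 1 rose (12 and 2 when adjusted over the list alone; camera adjusted p = 3.73e-05, and adjusted p = 0.0138 with an estimated correlation). The tropomyosin gene TPM1 fell 2.74-fold (-1.45 ± 0.16 SE), the integrin gene ITGB5 2.61-fold (-1.39 ± 0.16 SE), TAGLN, which encodes transgelin, 3.29-fold (-1.72 ± 0.34 SE) and the vinculin gene VCL 1.88-fold (-0.91 ± 0.14 SE), while the myosin light chain kinase gene MYLK rose 2.00-fold (1.00 ± 0.13 SE). The call of TAGLN was lost with uninduced arrays alone as controls. ITGB5 changed by -0.69 with the mean of its probe sets, and TIMP3 by 0.63 with an offset of 64.

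Of 19 TGF-beta response genes, 5 fell and 1 rose (7 and 1 when adjusted over the list alone). CCN2 fell 3.87-fold (-1.95 ± 0.23 SE), TGFBI, a matrix protein gene induced by TGF-beta, 3.58-fold (-1.84 ± 0.26 SE) and TGFB1I1 1.75-fold (-0.80 ± 0.14 SE), as did ID3 (-0.76 ± 0.19 SE) and SMAD6 (-0.45 ± 0.12 SE; named after its value was seen), while TGFB1 itself rose 1.43-fold (0.51 ± 0.13 SE). The call of ID3 was lost with no filter, no intensity trend, uninduced arrays alone as controls (-0.65) and without induced 24 h run 2 (-0.66), induced 72 h run 2 (-0.69), induced 0 h run 2 (-0.65) or uninduced 24 h run 2 (-0.64). That of TGFB1 was lost with values as given (0.42), with uninduced arrays alone as controls (0.47) and without induced 48 h run 1 (0.48), induced 0 h run 2 (0.46) or uninduced 24 h run 2 (0.49). With an offset of 64 TGFB1I1 changed by -0.46. Camera gave the list an adjusted p of 0.0163, but an adjusted p of 0.187 with an estimated correlation and 0.0508 without the array of uninduced 24 h run 2.

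Smaller upward shifts were seen in 2 metabolic lists, and neither held with an estimated correlation. Of 27 amino acid stress (ATF4) genes, 3 rose and 1 fell (6 and 2 when adjusted over the list alone), with CEBPB, a leucine zipper transcription factor, 1.65-fold higher (log2 change 0.72 ± 0.10 SE), DDIT4 1.81-fold higher (0.86 ± 0.19 SE), VEGFA, the vascular endothelial growth factor, 1.57-fold higher (0.65 ± 0.15 SE) and the amino acid transporter gene SLC7A1 1.32-fold lower (-0.40 ± 0.10 SE). The camera adjusted p of this list was 0.0136, and 0.309 with an estimated correlation. The calls of DDIT4, VEGFA and SLC7A1 were lost with uninduced arrays alone as controls, that of VEGFA also with values as given, those of DDIT4 and SLC7A1 also without the 2 arrays with the largest factors, and that of SLC7A1 also with the mean of its probe sets (-0.21), no intensity trend, or without induced 0 h run 1 (-0.35) or run 2 (-0.38). Of 36 oxidative phosphorylation genes, COX7C, a subunit of cytochrome oxidase, rose 1.39-fold (0.48 ± 0.10 SE) and 35 were not called (1 rose when adjusted over the list alone). Camera adjusted p was 0.00297 for a median change of 0.12 (0.02 with values as given, as for the ATF4 genes, whose median was 0.11), and adjusted p was 0.366 with an estimated correlation. With values as given the median of all genes was itself shifted by -0.07, and all 7 lists called in this comparison stayed called. Without the 2 arrays with the largest factors, both lists had an adjusted p of 0.0524, and with an offset of 64 DDIT4 changed by 0.50.

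**Figure D2:**
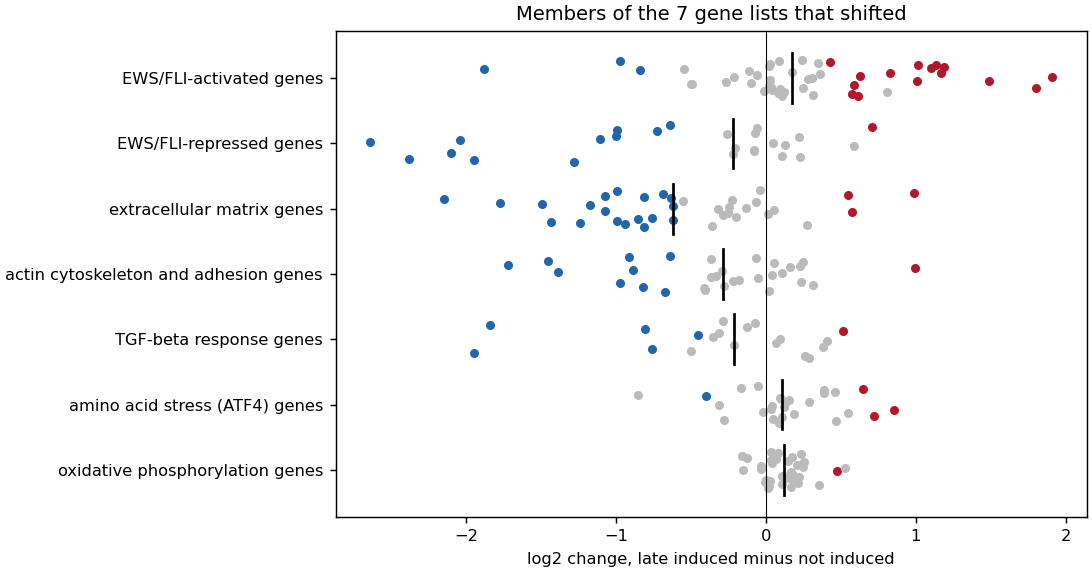
Log2 change between late induced and not induced arrays of each tested member of the 7 called gene lists. Each point is 1 gene, red for called and higher, blue for called and lower, grey for not called, and black bars mark list medians. Extracellular matrix genes had the lowest median, -0.62, and oxidative phosphorylation genes clustered near their median of 0.12.

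The other 17 lists were not called in this comparison. Among 18 mesenchymal lineage genes, NGFR, THY1 (2.58-fold) and CEBPB were higher while NT5E, CD44 and SPP1 (-1.15) were lower, the last gene of each side named after its value was seen (camera adjusted p = 0.626; 3 and 4 when adjusted over the list alone), and the median of 0.08 and the mean of -0.05 differed in sign. Of 19 neural and neuroendocrine genes, 2 fell, NES, which encodes nestin (2.83-fold), and GAP43 (2.20-fold), and 2 rose and 4 fell when adjusted over the list alone (adjusted p = 0.67; median 0.07, mean -0.08). Of 29 interferon response genes, only the class I antigen genes HLA-B (1.83-fold) and HLA-C (1.71-fold) fell (adjusted p = 0.204; 2 when adjusted over the list alone). Of 14 NF-kB and inflammatory genes, CXCL8, a neutrophil chemokine, fell 3.17-fold, ICAM1, an adhesion receptor, rose 2.15-fold and NFKB1 fell 1.43-fold (adjusted p = 0.345; 3 fell and 1 rose when adjusted over the list alone). Of 22 immediate-early and MAPK feedback genes, 4 fell, PHLDA1, IER3, JUN and DUSP5, and 2 rose, EGR1 and ETV5, of which DUSP5 and ETV5 were named after their values were seen (adjusted p = 0.329; 6 and 4 when adjusted over the list alone). Among 27 glycolysis and hypoxia genes, ADM and PFKFB3 fell and VEGFA rose (adjusted p = 0.636; 4 and 2 when adjusted over the list alone). CRYAB alone fell among 16 heat shock genes (adjusted p = 0.0606; 1 when adjusted over the list alone), and SC5D alone among 17 cholesterol synthesis genes (adjusted p = 0.0614; 3 when adjusted over the list alone).

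Cell division genes were not called. In limma 0 of 31 DNA replication genes and 0 of 36 mitosis genes passed, with 3 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.392 and 0.067). No gene passed among 13 p53-responsive, 19 endoplasmic reticulum stress, 30 cytosolic ribosomal protein, 28 MYC target and ribosome biogenesis and 11 histone genes (camera adjusted p = 0.621, 0.583, 0.271, 0.345 and 0.473). Over the 8 lists with 0 called members, 18 of 175 members had an unadjusted p under 0.05, and 0 passed in any of them when adjusted over the list alone. Markers of other cell types were few. Of 7 tested epithelial markers 0 were called (adjusted p = 0.329), and of 8 blood cell markers CD79A, a B-cell receptor component, was called, 2.68-fold higher (1 when adjusted over the list alone; adjusted p = 0.626). Endothelial and muscle markers had fewer than 5 tested members.

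The induced time course shows at which times these differences were detected, each against the same 2 arrays of induced 0 h. With 2 arrays against 2, a gene that was not called may still have changed. The simulated comparison of that size recovered 18.5% of genes changed by 1 on the log2 scale. At 6 h against 0 h, limma called 0 of 9277 genes, with 188 at an unadjusted p under 0.05. The 3 smallest p belonged to FLI1 (log2 change 0.85 ± 0.15 SE, n = 2 against 2), SGK1, a serum- and glucocorticoid-regulated kinase (1.02 ± 0.19 SE), and ADM (-1.16 ± 0.22 SE), each with an adjusted p of 0.234. FLI1 changed by 0.10 with the mean of its probe sets. Mitosis genes had a higher median than at 0 h by 0.11 (camera adjusted p = 0.0171; 0 of 36 called in limma, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05), with an adjusted p of 0.609 with an estimated correlation. Without induced 0 h run 1 their median was -0.10 (adjusted p = 0.331), without induced 6 h run 2 it was 0.01 (adjusted p = 0.875), and the call was also lost with values as given and with no intensity trend.

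At 12 h, 52 genes were called, 30 higher and 22 lower than at 0 h. NGFR was 3.45-fold higher (log2 change 1.79 ± 0.29 SE, n = 2 against 2), IL1RAP, an interleukin receptor subunit, 3.30-fold (1.72 ± 0.21 SE), RUNX3, a Runt family transcription factor, 3.05-fold (1.61 ± 0.21 SE), LBH 3.02-fold and the receptor tyrosine kinase gene ROR1 2.96-fold. DKK1 was 4.98-fold lower (-2.32 ± 0.26 SE), PGF 3.67-fold, ADM 3.66-fold, CCN2 3.61-fold and AFF1, a component of the elongation machinery, 3.29-fold lower. Their adjusted p ranged from 0.000436 to 0.0178. FLI1 (0.71 ± 0.15 SE, adjusted p = 0.052) and NKX2-2 (0.66 ± 0.16 SE, adjusted p = 0.0788) were not called. Values as given called 27 genes (12 higher and 15 lower), no intensity trend 30 and only the 4 arrays 22, and 18, 24 and 17 genes were called without induced 12 h run 1, induced 12 h run 2 and induced 0 h run 1. CCN2 was not called without induced 12 h run 1 (-1.95), induced 12 h run 2 (-1.75) or induced 0 h run 1 (-1.09), with no filter, no intensity trend or only the 4 arrays, NGFR not without induced 12 h run 1 (1.63) or induced 0 h run 1 (1.64), and ROR1 (0.85) and AFF1 (-0.88) not with the mean of all probe sets, with which IL1RAP changed by 1.10, PGF by -1.01 and FLI1 by 0.05. With an offset of 64 NGFR changed by 1.01 and ROR1 by 0.95.

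At 24 h, 221 genes were called, 103 higher and 118 lower than at 0 h. NGFR was 6.09-fold higher (log2 change 2.61 ± 0.29 SE, n = 2 against 2), AKR1B10 5.26-fold and IGFBP4 4.55-fold, and TRH (2.91 ± 0.36 SE) and ELN (2.39 ± 0.31 SE) rose from 0 h values at background (4.43 and 4.64). PGF was 8.55-fold lower on the probe set used (-3.10 ± 0.27 SE). ADM was 5.38-fold, LOX 5.07-fold, the membrane protein gene EMP1 5.01-fold and DKK1 4.80-fold lower. FLI1 rose 2.22-fold (1.15 ± 0.15 SE, adjusted p = 0.000431) and NKX2-2 1.84-fold (0.88 ± 0.16 SE, adjusted p = 0.00459, not called with values as given or without induced 24 h run 2). With the mean of all probe sets FLI1 was not called (0.36), and ELN changed by 1.48 and PGF by -1.48. With an offset of 64 the changes were 1.61 for TRH, 1.63 for NGFR, 1.52 for AKR1B10, 1.30 for ELN, 1.35 for IGFBP4 and -1.33 for EMP1. Values as given called 110 genes and no intensity trend 142, and 97, 92, 85 and 140 genes were called without induced 24 h run 1, induced 24 h run 2, induced 0 h run 1 and induced 0 h run 2. IGFBP4 was not called without induced 24 h run 2 (1.60) or induced 0 h run 1 (1.76).

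At 48 h, 195 genes were called, 79 higher and 116 lower than at 0 h. TRH (log2 change 4.25 ± 0.36 SE, n = 2 against 2) and ELN (2.36 ± 0.31 SE) rose from the same values at background, and IGFBP4 was 4.93-fold, FCGRT 4.58-fold and LBH 3.84-fold higher. IGFBP7 fell to background (-3.10 ± 0.37 SE, to a value of 4.23), and LOX was 7.82-fold, TGFBI 7.79-fold, CD44 7.10-fold and POSTN 5.89-fold lower. FLI1 was 1.97-fold (not called with the mean of its probe sets, 0.29) and NKX2-2 2.24-fold higher. With the mean of all probe sets ELN changed by 1.54 and CD44 by -1.80, and with an offset of 64 TRH by 2.72, ELN by 1.27, IGFBP4 by 1.42, IGFBP7 by -1.65 and POSTN by -1.66. Values as given called 113 genes, and 126, 100, 86 and 129 genes were called without induced 48 h run 1, induced 48 h run 2, induced 0 h run 1 and induced 0 h run 2.

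At 72 h, 211 genes were called, 67 higher and 144 lower than at 0 h. TRH (log2 change 2.93 ± 0.36 SE, n = 2 against 2) and ELN (1.97 ± 0.31 SE) again rose from background, and IGFBP4 was 3.47-fold, FCGRT 3.43-fold and LBH 3.29-fold higher. IGFBP7 fell to background (-3.11 ± 0.37 SE, to a value of 4.22). CD44 was 8.75-fold lower (-3.13 ± 0.27 SE), the collagenase gene MMP1 7.10-fold, TAGLN 6.94-fold and LOX 6.42-fold lower. FLI1 was 1.98-fold (not called with the mean of its probe sets, 0.25) and NKX2-2 2.54-fold higher. ELN changed by 1.06 and CD44 by -1.99 with the mean of all probe sets, and with an offset of 64 TRH by 1.61, ELN by 1.01, IGFBP4 by 1.04 and IGFBP7 by -1.65. Values as given, in which the median of all genes was shifted by -0.12, called 139 genes, 22 higher and 117 lower, and only the 4 arrays 123, so the share of higher genes was 15.8% with values as given in place of 31.8%. Without induced 72 h run 1 or induced 0 h run 1, 98 and 105 genes were called, and IGFBP4 was called in neither case (1.46 and 1.37).

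Over the whole induced course, the F-test in limma called 273 genes (179 with values as given). The smallest p belonged to LOX, MMP1, TGFBI, POSTN and NT5E, with adjusted p from 7.18e-08 to 1.33e-06. LOX changed by -0.17, -0.79, -2.34, -2.97 and -2.68 on the log2 scale at 6, 12, 24, 48 and 72 h, and MMP1 by 0.12, -0.21, -0.67, -2.30 and -2.83. TGFBI was lowest at 48 h (-2.96) and less reduced at 72 h (-1.55). POSTN changed by 0.16 and -0.10 at 6 and 12 h and by -1.16 at 24 h, and NT5E by -0.84 at 12 h.

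**Figure D3:**
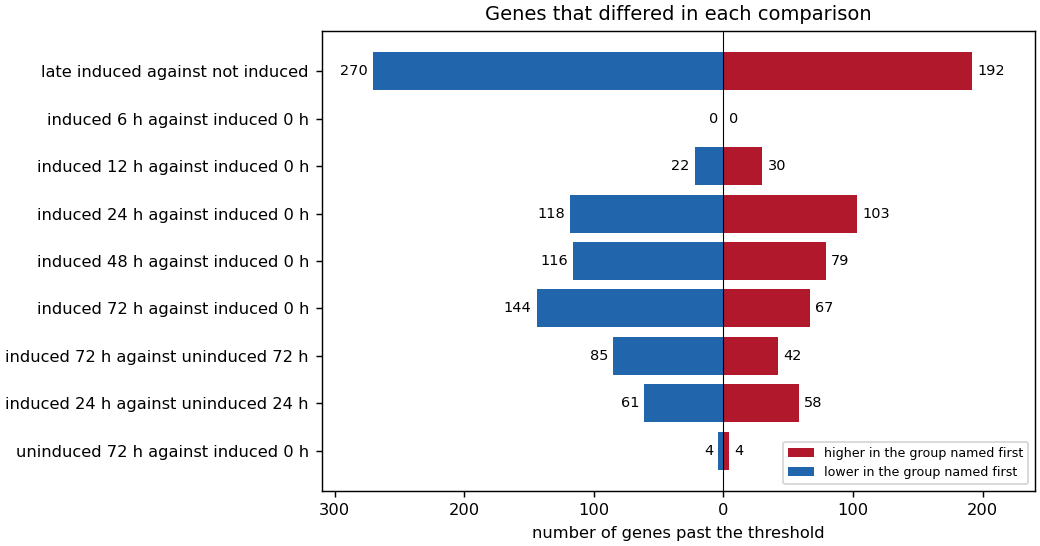
Number of genes past the threshold in each comparison, drawn to the right for genes higher and to the left for genes lower in the group named first. The induced series rises from 0 genes at 6 h to 52 at 12 h and about 200 from 24 h, while uninduced 72 h against induced 0 h has 8.

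Induced and uninduced cells were compared at a matched time of 72 h. TRH (log2 change 2.95 ± 0.36 SE, n = 2 against 2) and ELN (2.15 ± 0.31 SE) were higher in induced cells and at background in uninduced ones (4.41 and 4.46), and NGFR was 3.72-fold, FCGRT 3.70-fold and CES1 3.54-fold higher. IGFBP7 was lower (-2.98 ± 0.37 SE) and at background in induced cells (4.22), LOX was 6.99-fold (-2.81 ± 0.18 SE), MMP1 5.34-fold, CD44 5.30-fold and S100A10, a small calcium-binding family protein gene, 5.16-fold lower. FLI1 differed 1.54-fold without being called (0.62 ± 0.15 SE, adjusted p = 0.0629), and NKX2-2 was 2.35-fold higher (1.23 ± 0.16 SE, adjusted p = 0.000355, not called with values as given). In all, 127 genes were called, 42 higher and 85 lower. With no intensity trend 83 genes were called and with only the 4 arrays 57, and 46, 43 and 69 genes without induced 72 h run 1, uninduced 72 h run 1 and uninduced 72 h run 2. Values as given called 12 higher and 78 lower genes. NGFR was not called without uninduced 72 h run 1 (1.52), nor ELN with the mean of its probe sets (0.95), where CD44 changed by -1.50 and FLI1 by 0.21. With an offset of 64 TRH changed by 1.62, ELN by 1.07, NGFR by 1.02 and IGFBP7 by -1.58.

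The lists that moved at 72 h were largely those of the main comparison, which shares these arrays. TGF-beta response genes, called there, were not called at the matched 72 h. Of 19 members 2 fell, with a median of 0.01 (camera adjusted p = 0.325, and 0.399 with an estimated correlation). In uninduced 72 h against induced 0 h cells their median was -0.19 (camera adjusted p = 0.189). Extracellular matrix genes fell (12 of 36, with 1 that rose; 22 and 2 when adjusted over the list alone; camera adjusted p = 1.04e-19, and 0.0116 with an estimated correlation), led by MMP1, POSTN (5.01-fold), COL3A1 (3.03-fold) and COL1A2 (2.12-fold), while TIMP3 rose (0.91 ± 0.20 SE). The call of TIMP3 was lost without any of the 4 arrays (0.93 and 0.90 without induced run 1 and run 2, 0.89 and 0.93 without uninduced run 1 and run 2), and with no filter, values as given, the mean of its probe sets (0.78) or only the 4 arrays, and with an offset of 64 its change was 0.59. EWS/FLI-repressed genes fell (7 of 25; 11, with 2 that rose, when adjusted over the list alone; adjusted p = 1.3e-09, and 0.0123 with an estimated correlation), led by LOX, NT5E, CD44 and DKK1 (-1.57, not called without uninduced 72 h run 1, where it was -1.17); NT5E changed by -2.08, and by -1.20 with an offset of 64. EWS/FLI-activated genes rose (7 of 47, with 1 that fell; 15 and 6 when adjusted over the list alone; adjusted p = 8.72e-06, and 0.0362 with an estimated correlation), led by LBH, FCGRT and NKX2-2 against PHLDA1 (-2.11, and -1.39 with an offset of 64 or -1.20 with the mean of its probe sets). As above, these 2 lists and their counts are not independent evidence. Actin cytoskeleton and adhesion genes fell (5 of 30; 9, with 2 that rose, when adjusted over the list alone; adjusted p = 0.000446, and 0.0337 with an estimated correlation), namely TAGLN (4.72-fold), TPM1 (2.83-fold), ACTA2 (2.33-fold), ITGB5 (2.02-fold) and VCL (1.93-fold), the last named after its value was seen. ACTA2 was not called without induced run 1 (-1.23) or run 2 (-1.20) or uninduced run 1 (-1.08) or run 2 (-1.36), and ITGB5 not without induced run 1 (-0.58) or uninduced run 1 (-0.93) or run 2 (-1.09), nor with the mean of its probe sets (-0.27), values as given or only the 4 arrays. The call of ACTA2 was also lost with the mean of its probe sets (-0.87), and those of both genes with no filter and no intensity trend.

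Cholesterol synthesis genes had a lower level in induced than in uninduced cells at 72 h, with a median of -0.50. The ACTB 3' to 5' ratio, a measure of RNA integrity, also differed, at 1.40 and 1.53 on the uninduced arrays, the lowest of the series, and 1.74 and 1.63 on the induced ones. In limma 0 of the 17 members passed over all genes, with 9 at an unadjusted p under 0.05, and 8 fell when adjusted over the list alone (camera adjusted p = 0.000136, and 0.0207 with an estimated correlation). FDPS, which makes farnesyl diphosphate, had a log2 change of -0.60 ± 0.15 (SE), DHCR7, the last enzyme of the pathway, -0.75 ± 0.19 and LSS, lanosterol synthase, -0.79 ± 0.22. Without induced 72 h run 2 the list had an adjusted p of 0.0551. ATF4 genes (median 0.16, and 0.01 with values as given, CHAC1 alone of 27 called, 1.55 ± 0.31 SE; 4 when adjusted over the list alone) had an adjusted p of 0.000596, and 0.205 with an estimated correlation. Oxidative phosphorylation genes (median 0.09, COX7C alone of 36 called, 0.69 ± 0.15 SE; 2 when adjusted over the list alone) had an adjusted p of 0.0063, and 0.399 with an estimated correlation. Their median was -0.11 with values as given, where the median of all genes was shifted by -0.19, and the list was not called without induced 72 h run 1 (adjusted p = 0.105). CHAC1 was not called without induced run 1 (1.59) or run 2 (1.51) or uninduced run 1 (1.43) or run 2 (1.67) and changed by 0.75 with an offset of 64 (its uninduced value of 4.71 was at background), and COX7C not without induced run 1 (0.55) or uninduced run 1 (0.62) or run 2 (0.77), nor with any of no filter, values as given, the mean of its probe sets, no intensity trend and only the 4 arrays.

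At 24 h, 2 induced arrays were set against the lone uninduced array. AKR1B10 was 5.29-fold higher. NGFR (log2 change 3.55 ± 0.36 SE), TRH (2.98 ± 0.44 SE), TRPM4 (2.79 ± 0.43 SE) and ELN (2.52 ± 0.38 SE) were higher too, but at background on the uninduced array (4.13, 4.36, 4.43 and 4.52). PGF was 8.90-fold lower on the probe set used (-3.15 ± 0.33 SE). DKK1 was 8.29-fold, ADM 5.90-fold, PHLDA1 5.27-fold and CCN2 4.55-fold lower. FLI1 was 3.88-fold (1.96 ± 0.19 SE, not called with the mean of its probe sets, 0.63) and NKX2-2 2.45-fold higher (1.30 ± 0.19 SE), against an uninduced array that held the lowest FLI1 and NKX2-2 signals of the series and its highest ACTB 3' to 5' ratio (2.72), with a GAPDH ratio of 1.58. In all, 119 genes were called, 58 higher and 61 lower, with the spread of the lone array taken from other groups, so that a call not also made against 0 h, without that array, is not separable from a deviation of it. With the mean of all probe sets ELN changed by 1.32, PGF by -1.56 and PHLDA1 by -1.48, and with an offset of 64 NGFR by 1.95, TRH by 1.64, AKR1B10 by 1.53, ELN by 1.35, TRPM4 by a value between these last 2, and PHLDA1 by -1.59. Values as given called 46 genes, which left out NKX2-2, no intensity trend 72 genes, and a fit on only the 3 arrays 194, and 64 and 42 genes were called without induced 24 h run 1 and run 2, CCN2 in neither case (-2.08 and -2.29) nor with no intensity trend.

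Time in culture without induction was read from uninduced 72 h against induced 0 h. GNL3L, a nucleolar GTPase gene, was 2.87-fold higher (log2 change 1.52 ± 0.25 SE, n = 2 against 2), ASS1, which encodes argininosuccinate synthase, 2.44-fold (1.29 ± 0.22 SE), the fatty acid desaturase gene SCD 2.41-fold (1.27 ± 0.17 SE) and FDPS 1.82-fold (0.86 ± 0.15 SE). The LIM domain protein gene FHL2 was 3.86-fold lower (-1.95 ± 0.31 SE), CCK, the cholecystokinin gene, 2.69-fold (-1.43 ± 0.19 SE), the cystine transporter gene SLC7A11 2.55-fold lower (-1.35 ± 0.24 SE), and SGK1 was also lower (-1.32 ± 0.19 SE). These 8 were all the genes called, with 671 at an unadjusted p under 0.05. FLI1 differed by 0.37 ± 0.15 (SE, adjusted p = 0.606) and NKX2-2 by 0.11 ± 0.16 (SE, adjusted p = 0.939). With the mean of all probe sets GNL3L (0.99) and SLC7A11 (-0.58) were not called, and with an offset of 64 GNL3L changed by 0.96, FHL2 by -1.07 and CCK by -0.83. With values as given or only the 4 arrays 0 genes were called, with no intensity trend 1 and with no filter 3, and 0, 0, 2 and 0 genes without uninduced 72 h run 1, uninduced 72 h run 2, induced 0 h run 1 and induced 0 h run 2.

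Cholesterol synthesis genes rose in this comparison, by a median of 0.59 over 17 members. FDPS was called and 11 rose when adjusted over the list alone, among them HMGCS1 (log2 change 1.28 ± 0.30 SE), MSMO1 (1.22 ± 0.26 SE) and SQLE (0.65 ± 0.15 SE). The camera adjusted p was 7.82e-16, and 0.00095 with an estimated correlation. The GAPDH 3' to 5' signal ratio, a measure of RNA integrity, was among the lowest on the uninduced 72 h arrays, at 1.14 and 1.06, against 1.19 and 1.33 on the induced 0 h arrays. The ACTB ratio on the uninduced 72 h arrays, 1.40 and 1.53, was the lowest of the series, against 1.77 and 1.78 at induced 0 h. Mitosis genes had a median of 0.22 (0 of 36 called in limma, also when adjusted over the list alone, with 7 at an unadjusted p under 0.05; camera adjusted p = 2.6e-07), with an adjusted p of 0.398 with an estimated correlation and of 0.767 (median 0.05) without induced 0 h run 1.

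The effect of induction was compared between 72 h and 24 h, where it rests on the lone uninduced 24 h array. The interaction in limma called 0 genes, with 386 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152. This comparison was added after the data were seen. The 3 smallest p belonged to PKP1, a plakophilin gene (effect of 0.06 at 72 h and -1.16 at 24 h), FLI1 (0.62 and 1.96) and MMP1 (-2.42 and -0.72), all at that adjusted p. Without induced 72 h run 2 or uninduced 72 h run 1, 3 and 1 genes were called, none of them among these 3. With the mean of all probe sets the difference between the effects was 0.78 for PKP1 and -0.42 for FLI1, in place of 1.23 and -1.34. The FLI1 effect at 24 h stands against the lowest FLI1 signal of the series (349).

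Changes from arrays that were not shared could be compared across genes. Log2 changes of induced 48 h against induced 0 h and of induced 72 h against uninduced 72 h correlated with a Pearson r of 0.433 and a Spearman rho of 0.279 across 9277 genes, which are not independent replicates. Within runs the Pearson r was 0.225 and 0.204. Of the 127 genes called in the second comparison, 126 changed in the same direction in the first (99.2%), against 58.4% of all genes. The Wilson 95% interval of 95.7% to 99.9% takes genes as independent and does not measure the spread between arrays. Without induced 72 h run 2, which also changes the genes called, the share was 85.9%.

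The genes called at 72 h against uninduced cells were followed over the earlier times, on arrays outside that contrast. Those arrays entered the choice of the genes only through the shared estimate of the spread. The 42 higher genes changed by a median of 0.60 at 12 h, 0.95 at 24 h and 1.16 at 48 h against 0 h, and the 85 lower genes by -0.37, -0.94 and -0.98. All 6 medians lay beyond 95% of 10000 random lists of the same size and had camera p from 9.63e-06 to 0.00038 with an estimated correlation. At 6 h the medians were 0.07 and -0.09, also outside the middle 95% of random lists, but with p = 0.0855 and p = 0.11 with an estimated correlation. Without induced 0 h run 1 they were -0.02 and 0.00, and without induced 6 h run 2 they were 0.04 and -0.05. Leaving out an array of the 72 h comparison changes which genes are followed. The higher genes then had medians of 1.02 at 12 h and 1.47 at 24 h without induced 72 h run 1, of 0.37, 0.57 and 0.47 at 12, 24 and 48 h without induced 72 h run 2, and of 1.57 at 24 h without uninduced 72 h run 1. The lower genes had medians of -1.54 and -1.58 at 48 h without run 1 of induced and of uninduced 72 h. With an offset of 64 the higher genes changed by 0.37 at 12 h, and with values as given by 1.54 at 24 h.

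**Figure D4:**
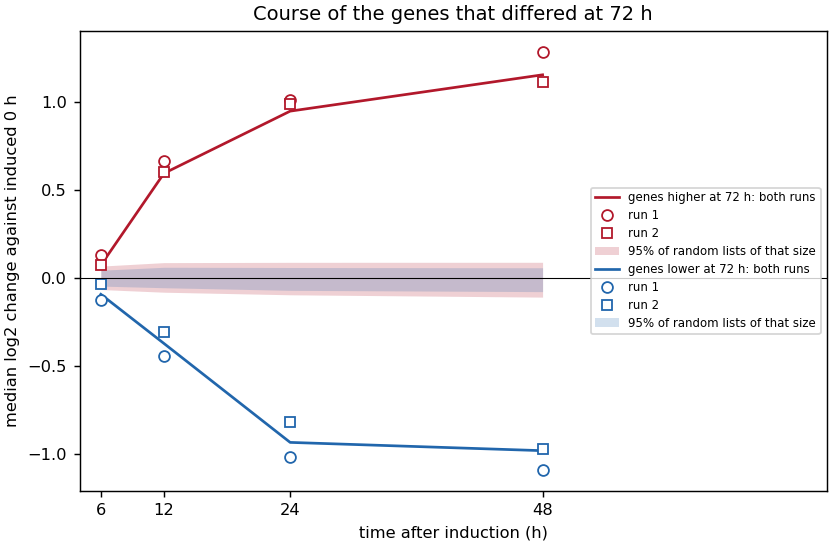
Median log2 change against induced 0 h of the 42 genes higher and the 85 genes lower in induced than in uninduced cells at 72 h, at 6, 12, 24 and 48 h. Lines show both runs, open circles and squares run 1 and run 2, and shaded bands the middle 95% of random lists of the same size. The 24 h medians were 0.95 and -0.94, outside the bands.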

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

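The tests without the 2 arrays with the largest rescaling factors and with genes chosen against induced 0 h alone were chosen only after the result was seen. In 54 groups of 4 to 10 values, 3 had an array far from the others, and chance alone flags about 1 in 20 such groups. In the arrays that were not induced, PGF had a normalized value of 8.06 on the run 2 array of uninduced 72 h, against 9.07 to 9.47 on the others. NKX2-2 had a normalized value of 7.03 on the uninduced 24 h array, against 7.44 to 7.56. The ACTB 3' to 5' signal ratio, a measure of RNA integrity, was 2.72 on the same uninduced 24 h array, against 1.40 to 1.78.

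A signal was also present in probe sets that stand outside the comparisons of genes. Of 1940 probe sets without a single gene symbol that were bright enough to test, 41 differed between late induced and not induced arrays in limma, 23 higher and 18 lower. The annotation used here lists no gene or several genes for each, and they are not reported one by one.

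The 462 genes that differed between late induced and not induced arrays were weighed against 3 other explanations. Over 100 splits, the real one and others drawn at random from the 462 possible, the highest other split called 109 genes. Only 1 of the 100 splits, the real one, reached the real count, so a random division of single arrays is not a likely source. The splits treat single arrays as exchangeable, while the 2 arrays of a group may not be separate cultures. They therefore cannot exclude differences between cultures. For each of the 462 genes, the change without the 2 arrays with the largest rescaling factors was divided by that with them. The median of these ratios was 0.983, so rescaling of those arrays is not a likely source. In their own direction, the same genes changed by a median of 0.0222 (0.08 and -0.00 in run 1 and run 2) between induced 0 h and uninduced 72 h, against 0.77 with induction. Both groups were among the controls that chose these genes, which works against genes moved by time, so that low value excludes nothing. For the 225 genes called against induced 0 h alone, 204 of them among the 462, the median was 0.26 (0.29 and 0.23 in run 1 and run 2) against 1.07 with induction, and 58 changed by at least 0.5 times as much without induction. These genes were chosen and read against the same 2 induced 0 h arrays, which raises that median even without an effect of time, so it decides nothing and a share of time in culture stays open. Time alone would leave no difference at a matched time, where 127 genes were called between induced and uninduced cells at 72 h. For these, time alone is not enough, but a response to induction is not settled. The 2 arrays per side may not be separate cultures. Their ACTB 3' to 5' ratios also differed, at 1.74 and 1.63 on the induced and 1.40 and 1.53 on the uninduced arrays. No array here separates an effect of EWS/FLI from one of the inducing agent.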

How the results depend on the processing

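The runs without the 2 arrays with the largest rescaling factors, the estimated correlation for the timing of the response, and all runs of the interaction were chosen only after the results were seen. Over 146 results for named genes, alternatives other than leaving out an array kept direction and side of the threshold in 1168 cases, lost the call in 77 and gained it in 1. Leaving out an array kept 785 and lost 71. For 17 results of lists, the counts were 138 kept and 12 lost, and 111 kept, 5 lost and 1 reversed. The reversed result was that of mitosis genes at 6 h, with medians from -0.10 without induced 0 h run 1 to 0.32 without induced 0 h run 2. Signal over background limits dim genes, and between 31.8% and 43.1% of probe sets per array had a signal under 16. Except where a smaller number of arrays or of genes accounts for a lost call, the cause was not tested.

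Values as given called 27 genes at 12 h, 110 at 24 h, 113 at 48 h, 139 at 72 h, 46 for induced against uninduced 24 h, 0 for uninduced 72 h against 0 h, 179 in the F-test and 0 lists at 6 h, and moved the higher genes at 6 h to a median of 0.0234. No intensity trend called 30 genes at 12 h, 142 at 24 h, 83 for induced against uninduced 72 h, 72 for induced against uninduced 24 h, 1 for uninduced 72 h against 0 h and 0 lists at 6 h. A fit on only the arrays compared called 22 genes at 12 h, 123 at 72 h, 57 for induced against uninduced 72 h, 194 for induced against uninduced 24 h and 0 for uninduced 72 h against 0 h. No filter called 3 genes for uninduced 72 h against 0 h and 2 lists at 6 h, and the stricter filter 3 lists at 6 h, as more or fewer genes were tested. The mean of all probe sets called 2 lists at 6 h. Uninduced arrays alone as controls called 296 genes in the main comparison. The estimated correlation called 4 lists in the main comparison, 1 in uninduced 72 h against 0 h and 0 at 6 h, and left the 6 h medians of 0.0730 and -0.0922 not called. The correlation between comparisons without shared arrays, across genes that are not independent replicates, was 0.385 with no filter, 0.511 with the stricter filter and 0.4997 with an offset of 64.

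Leaving out each array in turn gave 351 to 450 genes in the main comparison, 0 to 0 at 6 h, 17 to 41 at 12 h, 85 to 140 at 24 h, 86 to 129 at 48 h, 98 to 244 at 72 h and 210 to 310 in the F-test. It gave 43 to 170 genes for induced against uninduced 72 h, 42 to 64 for induced against uninduced 24 h and 0 to 2 for uninduced 72 h against 0 h, and 0 to 3 for the effect of induction at 72 h against 24 h. Called lists numbered 7 to 10 in the main comparison, 6 to 8 in induced against uninduced 72 h, 1 to 7 in uninduced 72 h against 0 h and 0 to 3 at 6 h. The correlation across genes ranged from 0.347 to 0.422 and the share in the same direction from 85.9% to 100%. The medians of the higher genes ranged from -0.0194 to 0.168 at 6 h, 0.37 to 1.02 at 12 h, 0.57 to 1.57 at 24 h and 0.47 to 1.63 at 48 h, and those of the lower genes from -0.135 to 0.00474, -0.48 to -0.32, -1.28 to -0.77 and -1.58 to -0.76. A lone array left in a group was assumed to vary like the other groups.

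With the run as a block the main comparison called 465 genes, the other comparisons 0, 58, 250, 212, 246, 143, 121 and 8 in the order of their times and controls, and the F-test 323, and it changed no count by more than 1.5 times. Over 21 pairs of the 7 groups with both runs, differences between run 1 and run 2 correlated at -0.09 to 0.40 across genes. The median was 0.12, and 11 of the pairs were above 0.1. The labels give only a run number, so run was left out of the main fits, although these values leave a shared effect of run possible. In 7 of 7 groups the best match among the other groups had the same run number, a hint from the data and not from the design.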

Other observations

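The tests on cholesterol synthesis genes and on mitosis genes were chosen only after the results were seen. Relative to induced 0 h, the list of cholesterol synthesis genes stood at 0.49 and 0.63 on the run 1 and run 2 arrays of uninduced 72 h, and at 0.17 on the uninduced 24 h array. In induced cells it stood at -0.17 and -0.11 at 6 h, -0.19 and -0.16 at 12 h, -0.26 and -0.10 at 24 h, 0.18 and 0.15 at 48 h and 0.35 and 0.23 at 72 h. By camera with an estimated correlation, these genes were higher than at induced 0 h in induced cells at 72 h (median 0.29, p = 0.00956) and 48 h (0.15, p = 0.0451), and not detectably different at 24 h (-0.02, p = 0.093). Their median was 0.49 higher in uninduced cells at 72 h than at 24 h and changed by -0.35 from uninduced to induced cells at 24 h. Both of these last values rest on the lone uninduced 24 h array, which had no second array to show its spread and had an ACTB 3' to 5' ratio of 2.72. SGK1 had group means of 8.76, 9.78, 9.57, 9.29, 8.54 and 7.71 at 0, 6, 12, 24, 48 and 72 h after induction, and 8.62 and 7.44 in uninduced cells at 24 and 72 h.

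The higher level of cholesterol synthesis genes in uninduced 72 h than in induced 0 h cells was weighed against technical sources. The lower of the differences within run 1 and run 2 was 0.56 (the other 0.72), so a single aberrant array is not a likely source. Among arrays with a GAPDH 3' to 5' ratio of at most 1.2, the 2 arrays of uninduced 72 h lay 0.27 above the highest of the 4 others, which argues against RNA integrity as far as that ratio measures it. By the ACTB 3' to 5' ratio the 2 arrays of uninduced 72 h stood apart, at 1.40 and 1.53 against 1.63 or more on every other array, so no matched array exists and RNA integrity stays open as a source. The list was also higher at 72 h than at 0 h in induced cells (median 0.29), so a rise over time did not need the lack of induction. Whether time in culture raised these genes stays open too.

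Mitosis genes were called higher at 6 h and in uninduced 72 h cells than at induced 0 h at the preset correlation only (adjusted p = 0.609 and 0.398 with an estimated correlation, with 0 of 36 members called), and the run 1 array of induced 0 h may account for both. That array had a list value of -0.21, the other induced 0 h array 0.21. Without it the smaller adjusted p of the list in these comparisons was 0.331, with medians of -0.10 at 6 h and 0.05 at uninduced 72 h. The result is consistent with a property of that array, technical or biological, and gives no ground for a change in cell division.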
